A study of Mus musculus with 5 samples.

How the data were processed

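Total RNA from mouse liver was labelled with biotin and hybridised to Affymetrix expression arrays, 1 array per sample, per the labels. The values used are log2 expression values deposited by the authors, made with RMA per the submitters' processing notes, which corrects background, normalizes quantiles across arrays and summarises the probes of each probe set. The version of RMA and its settings are not given in the sources used here, and the scanner intensities were not used here. Quantile normalization gives the arrays nearly the same distribution, so that a change shared by most genes cannot be seen. RMA values of dim probe sets are compressed towards a floor, so folds of dim genes are understated. The array medians over all probe sets were 6.305 (control), 6.329 and 6.262 (dysplasia), and 6.26 and 6.268 (tumor). That the scale is log2 was read from the values, which lay between 3.76 and 14.61.

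The labels give a control group of 1 array and groups with dysplasia and with tumor of 2 arrays each, all from male mice aged 20 months. The labels do not state the strain, or that the arrays of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical. Tumor samples are labelled by the mouse's tumor, and whether the RNA came from the tumor itself or from liver beside it is not stated. The study's design text names infected against control mice as comparison 1 and mice with tumors against mice with infection only as comparison 2. Comparison 1 was read as the dysplasia arrays against the control array, and the readings with all 4 infected arrays and with the tumor arrays were run as alternatives.

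The table held 45101 probe sets, of which 64 were control probe sets. The platform annotation, which can be old, gave 34958 probe sets with 1 gene symbol, 932 with several and 9211 with none. Symbols were updated by gene ID to the RefSeq gene table of the GRCm38.p6 assembly, used for names only, which matched 34754 of the probe sets with 1 gene. Each gene was represented by the probe set with the highest mean over the 5 arrays among probe sets with exactly 1 gene, which left 18193 genes.

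Genes were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on 3 groups over all 5 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The fit had 2 residual degrees of freedom per gene and a prior of 2.87 degrees of freedom, and the lone control array was assumed to vary like the arrays of the other groups. All tests were two-sided. An exact permutation test of 2 arrays against 2, or of 1 against 2, cannot give a p under 0.333. A size rule without a test counted genes for which every array of 1 group lay at least 1 log2 unit, 2-fold, on the same side of every array of the other. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 drew the plots.

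The comparisons, alternatives, 30 gene lists and the rule for named genes were set before the data were examined. The lists cover immune response, cell types of liver, blood and neighbouring organs, cell division, liver tumors, liver zones, sex-biased expression, bile acid, drug and lipid metabolism, stress responses and the circadian clock. They held 626 members, of which 561 were measured by a probe set with 1 gene, and the other members were not analysed here. Some genes stand in more than 1 list, such as Slco1a1, Abcc4 and Lcn2. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 30 lists within a comparison, with the correlation estimated from the data and fry as alternatives. Camera asks whether a list moved relative to the other genes, and fry whether its genes moved, on balance, in 1 direction. A list of 34 skeletal muscle markers was written after the values were seen.

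The rule for named genes took, per comparison and direction, the 12 genes with the largest log2 difference among those past the threshold with no overlap between the groups. Where fewer than 12 passed, the rest were the genes with the largest difference in that direction among the 200 with the smallest unadjusted p, reported as values that did not pass. Immunoglobulin genes were kept but called uncertain, and predicted genes and clones were skipped. For each list, up to 4 members with the smallest p were named in addition.

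The tests were tried on simulated data with the real genes' means. In 10 simulations over 18193 genes, changes of 1, 2 and 4 log2 units were called for 3.43%, 75.1% and 97.6% of changed genes in comparison 1, and for 21.5%, 88.2% and 97.7% in comparison 2. All simulated arrays had the same spread for a gene. The root mean square difference was 0.416 between the real dysplasia arrays and 0.2445 between the tumor arrays, so these shares may not hold for them. In comparison 2, a list of 20 genes shifted by 0.5 was called by camera with the preset correlation in 20 of 20 simulations, with 1 false call, and with an estimated correlation in 0 of 20. The simulated genes were independent of each other. In the real lists the estimated correlation reached 0.751 (neutrophil markers), so the count of false calls may not hold for them. With an estimated correlation camera thus had little power here, and a list that did not pass by it may still have shifted. Fry was not tried on simulated data.

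Alternatives changed 1 choice at a time: the mean of all probe sets of a gene, all probe sets tested singly, the lower 40% of genes by mean left out, a repeated quantile normalization, median centring, an intensity trend or robust prior in eBayes, and other thresholds. Further alternatives were other readings of the infected group, only the control and dysplasia arrays in the fit, the replicate number as a block, and each dysplasia or tumor array left out in turn. The control array cannot be left out of comparison 1. With 1 array left out, the fit had 1 residual degree of freedom, the spread came from the other group of 2 arrays alone, and the lone array was assumed to vary like that group.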

Results

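Liver RNA from male mice aged 20 months was measured on 5 arrays, 1 array from a sham-inoculated control mouse, 2 from mice infected with Helicobacter hepaticus whose liver showed dysplasia, and 2 from infected mice with a liver tumor. Helicobacter hepaticus is a bacterium that colonises the intestine and liver of mice and is linked to chronic hepatitis and liver tumors in susceptible strains. Dysplasia is a disordered growth of cells that can precede a tumor. The array values ran from 3.76 to 14.61 on the log2 scale, and the median over all probe sets lay between 6.26 and 6.33 on the 5 arrays. The number of arrays limits the precision of every comparison, and the control group, with 1 array, has no replicate. Whether the 2 arrays of a group came from separate mice is not stated.

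Dysplasia array 1 stood apart from the other infected arrays. Across 18193 genes its root mean square difference from each of the other 4 arrays was 0.408 to 0.423 log2 units, while dysplasia array 2 and tumor array 1 differed by 0.188, the smallest distance among the 10 pairs of arrays. Between the 2 dysplasia arrays 563 genes differed by at least 2-fold, and between the 2 tumor arrays 141 did. The probe sets for 18S ribosomal RNA averaged 7.39 on the control array and 11.16 to 12.86 on the infected arrays. The probe sets for the poly-A RNAs that are added to a sample during labelling averaged 12.9 on tumor array 2 and 7.42 to 9.84 on the other arrays.

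Comparison 1 asked how the liver of infected mice differed from that of the control mouse, and was read from the 2 dysplasia arrays against the control array. Target genes of beta-catenin and other pericentral genes, which hepatocytes around the central vein express, rose by a mean of 0.97 log2 units in the dysplasia arrays, and genes of the unfolded protein response rose by a mean of 0.55. For both lists adjusted p = 3.55e-10 by limma's camera test with its preset correlation, and adjusted p = 0.531 with an estimated correlation. Lists of interferon, MHC class II, acute phase, macrophage, matrix and NRF2 genes also rose (adjusted p from 0.531 to 0.804 with an estimated correlation). Fatty acid synthesis genes fell by a mean of 0.34 (adjusted p = 0.00187 with the preset correlation, adjusted p = 0.531 with an estimated correlation). Among single genes only Myh1, a myosin heavy chain of fast skeletal muscle, fell, at 9.77 on the control array and 4.62 ± 0.11 (SD, n = 2) on the dysplasia arrays (35.5-fold, limma adjusted p = 0.0266). The largest difference upward was in Sult1e1, the estrogen sulfotransferase, at 5.81 on the control array and 10.24 ± 0.02 (SD, n = 2) on the dysplasia arrays, which did not pass (adjusted p = 0.358).

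The 12 genes named as higher in comparison 1 lay 3.42- to 21.6-fold above the control array by the mean of the dysplasia arrays, with both of these arrays higher in every case, and 0 of the 12 passed the test (limma adjusted p from 0.358 to 0.67). After Sult1e1, with a log2 difference of 4.43 (SE 0.42), came Rragd, a GTPase of amino acid signalling to mTOR, with 3.37 (SE 0.74). That difference rested on 1 probe set, since the gene's other, dimmer probe sets gave 0.04 and −0.36, and the mean of all its probe sets 1.01. Saa3, an acute phase protein, lay higher by 2.91 (SE 0.47, and 1.47 with the tumor arrays against the control) and Hamp, which encodes the iron-regulating hormone hepcidin, by 2.25 (SE 0.22). Casp4 and Casp12, both inflammatory caspases, lay higher by 2.85 and 1.77 (Casp12 by 2.71 with the mean of all its probe sets). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, lay higher by 2.65. Ltb, the cytokine lymphotoxin beta, lay higher by 2.12, and Tnfaip3, an inhibitor of NF-kappa B signalling, by 2.01 (1.11 with the mean of all its probe sets). Jun, a subunit of the AP-1 transcription factor, lay higher by 2.01, the matricellular protein gene Ccn2 by 1.94 and the glutathione transferase gene Gstm2 by 1.92. Casp4 and Gstm2 came under the threshold without dysplasia array 2 (adjusted p = 0.0245 and 0.035), where 1 array is set against 1 and only the 2 tumor arrays give the spread, so the spread between the dysplasia arrays is left out.

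Of the 12 genes named as lower in comparison 1, 8 encode proteins of skeletal muscle. Myh1 fell by 5.15 log2 units (SE 0.19), and a dimmer probe set of the same gene showed −5.92 while the dimmest of its 3 probe sets showed −0.09. Acta1, skeletal muscle actin, differed by −2.69 (adjusted p = 0.0759), Tnnc2, fast troponin C, by −2.89, and Tnni2, Mylpf, Myh2, Ckm and Smpx by −1.36 to −1.90, with no pass, although a dimmer probe set of Ckm gave 0.06. With the mean of all probe sets Ckm was at −0.68 and Tnni2 at −1.09. The other 4 were Tcf24 (−2.32), the melanin synthesis gene Dct (−1.70), the hepatocyte anion transporter gene Slco1a1 (−1.45) and the macrophage scavenger receptor gene Cd163 (−1.36). On the tumor arrays Myh1 lay at 4.78 and 4.49 and Acta1 at 5.59 and 5.68. Of 34 skeletal muscle markers, a list written after the values were seen, 32 were highest on the control array. The call of Myh1 was lost without dysplasia array 1 (adjusted p = 0.0951, with the spread from the tumor arrays alone), without either tumor array or with only the control and dysplasia arrays in the fit (0.233), and after centring of each array on its median (0.0556), with differences of −5.14 to −5.23 in these settings. Myh1 was not tested once dim genes were left out. Acta1 and Tnnc2 came under it as well without dysplasia array 2 (adjusted p = 0.0284 and 0.035), again with the spread of the tumor arrays alone.

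**Figure D1:**
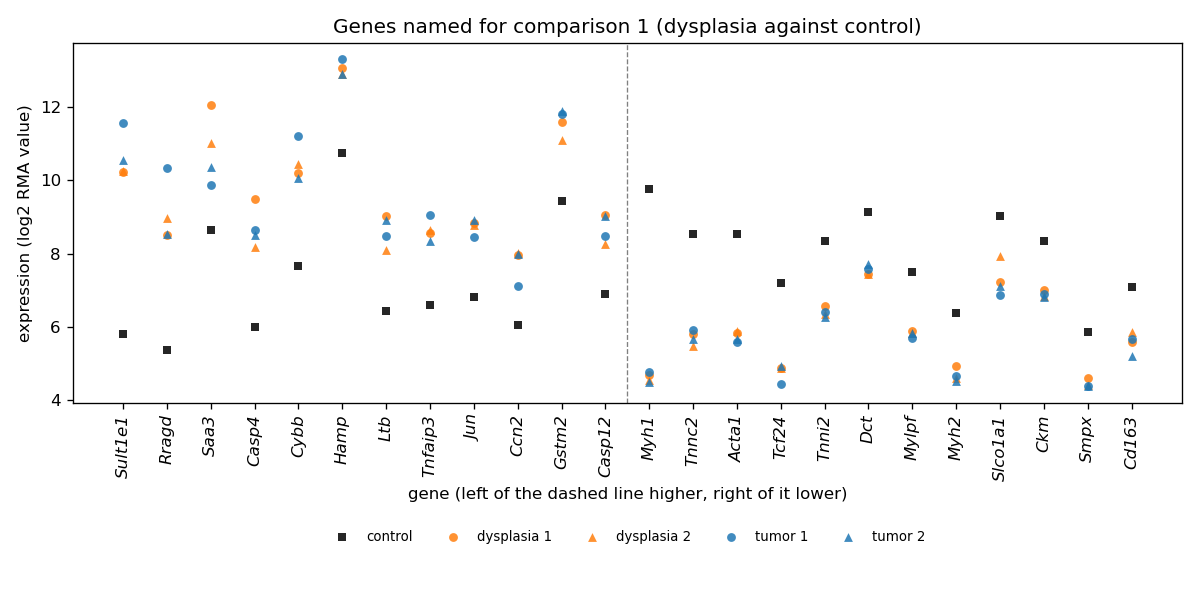
Expression (log2 RMA value, vertical axis) on each of the 5 arrays for the 12 genes named as higher and the 12 named as lower in comparison 1 (horizontal axis, divided by the dashed line). The control array is a black square, dysplasia arrays are orange and tumor arrays blue, with circles for array 1 and triangles for array 2 of a group. Myh1 lies at 9.77 on the control array and between 4.49 and 4.78 on the 4 infected arrays, and Sult1e1 at 5.81 on the control array and between 10.23 and 11.56 on the infected arrays.

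Of the immune gene lists 4, those of interferon, MHC class II, acute phase and macrophage genes, rose in the dysplasia arrays, with 0 members past the threshold over all genes in each. Of 28 interferon response genes 23 lay higher and the list rose by a mean of 0.38 (adjusted p = 0.000133 with the preset correlation, adjusted p = 0.531 with an estimated correlation), with 0 members past when adjusted over the list alone. Psmb9, a subunit of the immunoproteasome, lay higher by 0.91 and Ifit2 by 0.85, while Rsad2, an antiviral gene, lay lower at −0.66. The MHC class II list rose by a mean of 0.45 (adjusted p = 0.00417, and adjusted p = 0.634 with an estimated correlation), with 6 of 10 members higher. Adjusted over the list alone 4 passed, among them the invariant chain gene Cd74 (1.55) and H2-Ab1 (1.18). Without dysplasia array 2 the list no longer passed, with a mean of 0.37 (adjusted p = 0.056), and with dim genes left out the mean was 0.81. Acute phase genes rose by a mean of 0.67 with a median of 0.19 (adjusted p = 0.00187, and adjusted p = 0.804 with an estimated correlation), and Saa3 and Hamp passed when adjusted over the list alone. The mean of the acute phase list was 0.15 without dysplasia array 1 (adjusted p = 0.356) and 1.18 without dysplasia array 2. Its call was lost with all 4 infected arrays against the control, where the mean was 0.39 (adjusted p = 0.238). With the tumor arrays against the control the acute phase mean was 0.11, and the test pointed downward with no pass (adjusted p = 0.753). Macrophage and Kupffer cell markers rose by a mean of 0.23 with 16 of 22 members higher (adjusted p = 0.00232, and adjusted p = 0.531 with an estimated correlation), and 0 members passed when adjusted over the list alone. Lyz2, the lysozyme of myeloid cells, lay at 0.75 and Fcgr3 at 0.70. With the tumor arrays against the control the means were 0.77 for the interferon, 1.03 for the MHC class II and 0.78 for the macrophage list. With all 4 infected arrays they were 0.58, 0.74 and 0.50. These calls were kept with the preset correlation only. For the tumor arrays against the control, adjusted p = 0.624 for each of the 3 lists with an estimated correlation.

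Stress and signalling lists rose as well, again with 0 members past over all genes. All 20 unfolded protein response genes lay higher (adjusted p = 0.531 with an estimated correlation). Sdf2l1 (1.29), Pdia4 (0.88), Trib3 (0.74) and Pdia6 (0.67) passed when adjusted over the list alone. The call was lost with the tumor arrays against the control, where the mean was 0.14 (adjusted p = 0.121), and with all 4 infected arrays the mean was 0.35. Genes of NRF2 and glutathione metabolism rose by a mean of 0.39 (adjusted p = 0.00107, and adjusted p = 0.531 with an estimated correlation), and Gstm3 (1.22), the exporter gene Abcc4 (1.45) and Srxn1 (0.68) passed when adjusted over the list alone. The value of Srxn1 rested on 1 probe set, since its other 3 gave 0.03, 0.02 and −0.14. Without dysplasia array 2 the mean was 0.26 (adjusted p = 0.124). Immediate early genes rose by a mean of 0.58 with a median of 0.22 (adjusted p = 0.00204, and adjusted p = 0.531 with an estimated correlation), and Jun and Ccn2 passed when adjusted over the list alone. Genes of the p53 and DNA damage response rose by a mean of 0.25 (adjusted p = 0.0144, and adjusted p = 0.673 with an estimated correlation), and the cell cycle inhibitor gene Cdkn1a (1.01) and Btg2 (0.85) passed when adjusted over the list alone. The p53 list had a mean of 0.41 without dysplasia array 1 and of 0.08 without dysplasia array 2 (adjusted p = 0.668). Its call was lost with the mean of all probe sets of a gene, where the list mean was 0.17 (adjusted p = 0.0536). With the tumor arrays against the control the means were 0.87 for NRF2 genes (0.63 with all 4 infected arrays), 0.38 for the p53 list and 0.30 for immediate early genes. The calls were kept with the preset correlation, while for each of these lists adjusted p = 0.624 with an estimated correlation.

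Among the lists of liver zones, matrix and liver tumor markers, 18 of 19 pericentral and beta-catenin target genes lay higher in the dysplasia arrays (adjusted p = 0.531 with an estimated correlation). Over all genes 0 passed. Znrf3 (1.28), a feedback inhibitor of Wnt signalling, Ahr (1.41), the aryl hydrocarbon receptor, and Lect2 (1.09) passed when adjusted over the list alone, although the other, dimmer probe set of Znrf3 gave −0.18. The mean of the pericentral list was 0.57 without dysplasia array 1 and 0.64 with the tumor arrays against the control. The call was kept with the preset correlation. With an estimated correlation, adjusted p = 0.624 for the tumor arrays against the control. Stellate cell and matrix genes rose by a mean of 0.48 with 21 of 24 members higher (adjusted p = 0.00232, and adjusted p = 0.79 with an estimated correlation), and 0 passed over all genes or when adjusted over the list alone. The basement membrane collagen gene Col4a1 lay at 1.69 and the proteoglycan gene Dcn at 0.92 (−0.25 in a dim probe set). The matrix mean was 0.97 with the tumor arrays against the control and 0.73 with all 4 infected arrays. Fetal liver and liver tumor markers rose by a mean of 0.57 (adjusted p = 0.0056, and adjusted p = 0.736 with an estimated correlation), with 0 past over all genes. Lgals3 (0.69) and Abcc4, also a member of the NRF2 list, passed when adjusted over the list alone. The median was 0.26, with 16 of 21 members higher. The fetal liver genes Afp and Gpc3 hardly moved, at 5.35 and 6.27 on the control array. On the dysplasia arrays Afp lay at 5.54 and 5.31 and Gpc3 at 6.52 and 6.29. Ly6d, another member, lay at 7.61 on the control array and at 11.99 and 7.61 on the dysplasia arrays. The mean of this list was 0.24 without dysplasia array 1 (adjusted p = 0.12) and 0.89 without dysplasia array 2. The call was lost with the tumor arrays against the control, where the mean was 0.51 (adjusted p = 0.0658).

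The lists that fell were those of fatty acid synthesis and of genes with male-biased expression in liver, with 0 members past over all genes. Of 17 fatty acid synthesis genes 13 lay lower (adjusted p = 0.531 with an estimated correlation). Acacb, an acetyl-CoA carboxylase, at −0.92 passed when adjusted over the list alone, beside −0.49 for the fatty acid synthase gene Fasn and 0.56 for the triglyceride synthesis gene Dgat2. The mean of the list was −0.15 without dysplasia array 1 (adjusted p = 0.0783) and −0.53 without dysplasia array 2, and −0.02 with all 4 infected arrays against the control (adjusted p = 0.983). With the tumor arrays against the control the direction was reversed, with a mean of 0.30 (adjusted p = 0.00833 with the preset correlation, adjusted p = 0.624 with an estimated correlation). Male-biased genes fell by a mean of 0.41 with a median of −0.09 (adjusted p = 0.00415, and adjusted p = 0.531 with an estimated correlation), with 15 of 19 lower and 0 past when adjusted over the list alone. Slco1a1 was at −1.45 and the complement gene C6 at 0.53. The male-biased mean was −0.18 without dysplasia array 1 (adjusted p = 0.0783) and −0.64 without dysplasia array 2. The male-biased call was lost with the tumor arrays against the control, where the mean was −0.27 (adjusted p = 0.106).

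The other 17 lists did not pass in comparison 1, and the smallest adjusted p among them was 0.0825. Mean differences were 0.37 for neutrophil markers, 0.22 for cell division genes, 0.21 for bile duct and progenitor cell markers, 0.18 for inflammatory cytokines and chemokines, 0.17 for circadian clock genes and 0.08 for fatty acid oxidation genes. They were −0.003 for T and NK cell markers, −0.05 for endothelial markers, −0.15 for periportal genes, −0.18 for cholesterol synthesis genes, −0.21 for adipose and pancreas markers and −0.32 for erythroid markers. Within the uncalled lists, Pck1 (1.20), the control enzyme of gluconeogenesis, Cyp7a1 (0.88), the rate-limiting enzyme of bile acid synthesis, the bile acid and lipid transporter genes Slco1b2 (0.63) and Abcb4 (0.70), and Slco1a1 (−1.45) passed when adjusted over the list alone. So did the xenobiotic metabolism genes Fmo1 (0.95), Cyp2c39 (0.80) and Cyp2c38 (0.72), and 0 of these genes passed over all genes. Dimmer probe sets lay the other way for Pck1 (−0.25) and Slco1b2 (−0.32, −0.13 and −0.09). Xenobiotic metabolism genes had a mean of 0.05. Clock genes moved both ways, with 10 higher and 8 lower, among them Per1 (0.51), Cry1 (−0.59) and Npas2 (−0.63, and 0.12 in a dimmer probe set). A list mean can hide such opposite changes, so the small clock mean does not show that these genes were unchanged. Median, mean and test differed in sign for bile acid genes (median 0.06, mean −0.07, test upward), B and plasma cell markers (0.02, −0.04, downward), female-biased genes (0.01, −0.24, downward) and hepatocyte plasma proteins (−0.01, 0.01, upward). The B and plasma cell list holds the immunoglobulin gene Ighm at −1.23, while the other probe sets of Ighm ranged from −1.27 to 1.65. The direction of that list is therefore uncertain.

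Several of these 17 lists came under the threshold in comparison 1 once 1 dysplasia array was left out, where the tumor arrays alone give the spread. With array 2 left out these were neutrophil markers (mean 0.88, adjusted p = 3.67e-05), cell division genes (0.49, 2.75e-05), bile duct and progenitor cell markers (0.58, 0.0272) and cytokines and chemokines (0.30, 0.0349). Endothelial markers (−0.27, 0.00394), periportal genes (−0.42, 0.00983), cholesterol synthesis genes (−0.31, 0.00453), erythroid markers (−0.47, 0.0331), bile acid genes (−0.42, 0.0309) and fatty acid oxidation genes (−0.03, 0.0332) did so downward. With array 1 left out, xenobiotic metabolism genes (mean 0.33, adjusted p = 0.000524), bile acid genes (0.29, 0.0072) and fatty acid oxidation genes (0.19, 0.0315) did so upward. Fatty acid oxidation genes had a mean of 0.36 with the tumor arrays against the control (adjusted p = 0.0358, and adjusted p = 0.745 with an estimated correlation). Erythroid markers had −0.55 with dim genes left out (adjusted p = 0.0272). Female-biased genes came under the threshold with dim genes left out (mean −0.31, adjusted p = 0.0221), and cell division genes after quantile normalization again (0.23, 0.0109). Cholesterol synthesis genes did so with dim genes left out (−0.18, 0.0161), with the mean of all probe sets (−0.21, 0.0419) and after quantile normalization again (−0.26, 0.00651). Adipose and pancreas markers did so with the tumor arrays (−0.18, 0.0397, and 0.624 with an estimated correlation) or all 4 infected arrays (−0.19, 0.0387) against the control.

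By size alone, 96 genes lay at least 2-fold from the control on both dysplasia arrays, 71 higher and 25 lower, and 12 of the 25 were skeletal muscle markers. Beyond the genes already named, the 71 included Casp1, Tlr2, Icam1, Nfkbia and Ubd, which were chosen after their values were seen. The limma test called 1 gene at an adjusted p under 0.05, while 1236 genes had an unadjusted p under 0.05 (897 higher and 339 lower, against 910 by chance). After quantile normalization again the split was 552 higher and 608 lower, while after median centring it was 973 higher and 352 lower. Whether higher genes were in excess thus depended on the normalization. For 11040 genes (60.7%) the dysplasia arrays lay on 1 side of the control, a share that chance puts at 66.7%. Camera with an estimated correlation and fry each called 0 of the 30 lists. With an estimated correlation camera also called 0 of 20 shifted lists in the simulations of comparison 2. Its count therefore cannot tell shifted lists from unshifted ones, and fry was not tried on simulated data. The count of called genes was 42 without dysplasia array 2, with 1 array against 1 and the spread from the tumor arrays alone, and 0 without any other single infected array. The size count was 218 without dysplasia array 1 and 528 without dysplasia array 2. It can only stay or rise when an array is left out, since fewer arrays must then meet the rule. The count of called lists was 20 in place of 13 without dysplasia array 2.

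**Figure D2:**
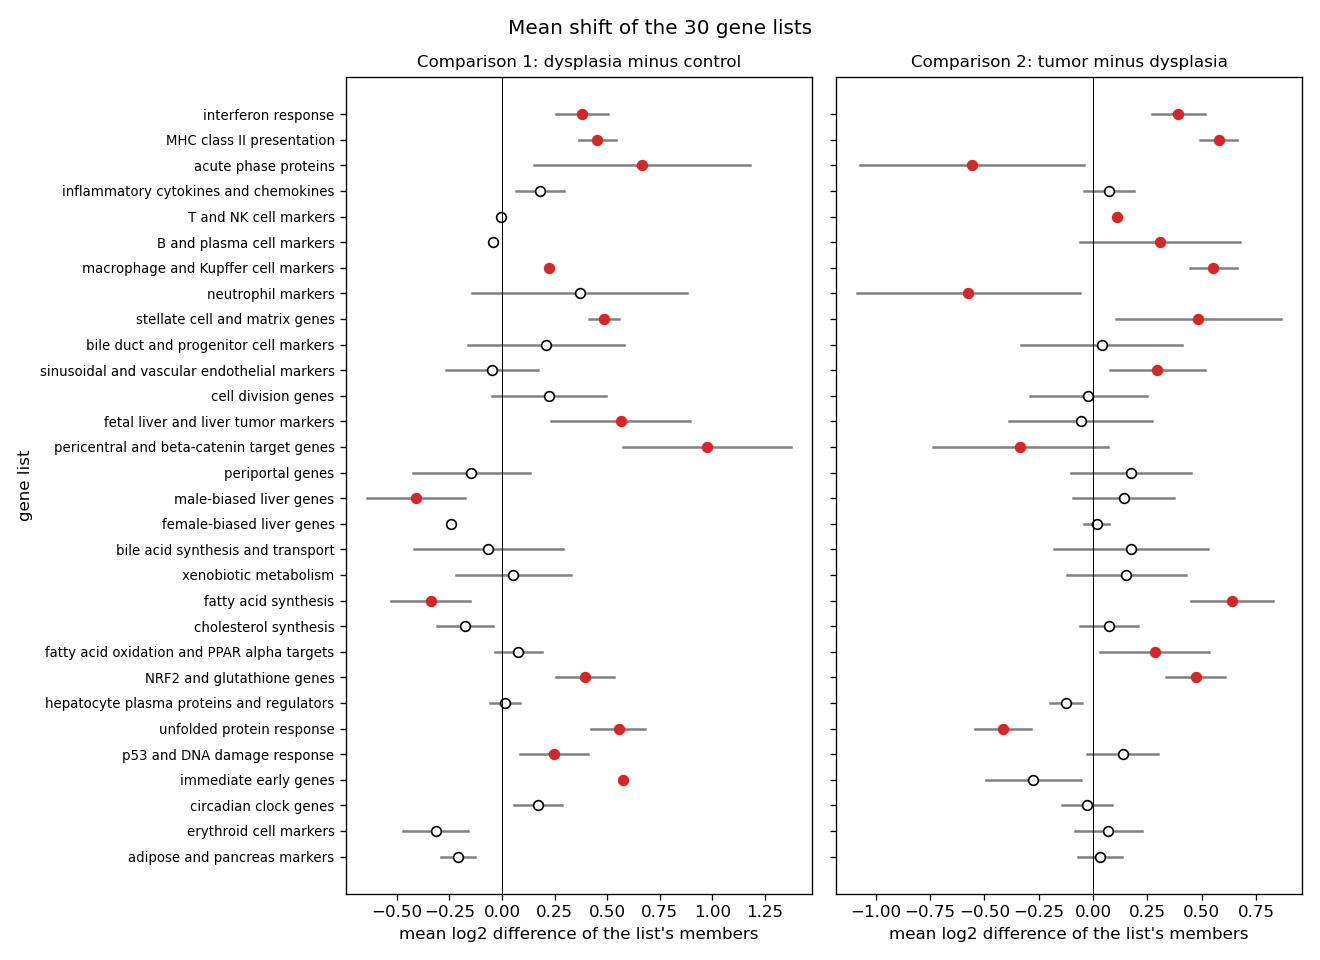
Mean log2 difference (horizontal axes) of the members of each of the 30 gene lists (vertical axis) in comparison 1, dysplasia minus control, and comparison 2, tumor minus dysplasia. Filled red circles mark lists past an adjusted p of 0.05 by camera with the preset correlation, open circles the others, and grey lines the range when 1 dysplasia or tumor array is left out. Fatty acid synthesis lies at −0.34 in comparison 1 and 0.64 in comparison 2, and the unfolded protein response at 0.55 and −0.42. The comparisons share the dysplasia arrays with opposite sign, so a shift of these arrays alone gives opposite differences.

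Comparison 2 asked how mice with tumors differed from mice with infection only, the 2 tumor arrays against the 2 dysplasia arrays. Genes of fatty acid synthesis rose by a mean of 0.64 log2 units in the tumor arrays, with all 17 members higher (adjusted p = 1.9e-15 with the preset correlation, adjusted p = 0.387 with an estimated correlation), and macrophage markers rose by a mean of 0.55 (adjusted p = 8.32e-14, and adjusted p = 0.387 with an estimated correlation). MHC class II and interferon genes also rose (for each adjusted p = 0.443 with an estimated correlation). Unfolded protein response genes fell by a mean of 0.42, with all 20 members lower (adjusted p = 1.11e-10, and adjusted p = 0.504 with an estimated correlation). The largest single difference was in Cidea, a lipid droplet protein, at 5.97 ± 0.58 (SD, n = 2) on the dysplasia arrays and 8.68 ± 1.56 (SD, n = 2) on the tumor arrays, 6.55-fold. Its size and rank rested on tumor array 2, without which the log2 difference was 1.60, against 1.65 for Me1. No single gene passed the test (limma, smallest adjusted p = 0.937).

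The 12 genes named as higher lay 2.21- to 6.55-fold higher on the tumor arrays, with no overlap between the groups, and 0 passed. After Cidea, with a log2 difference of 2.71 (SE 0.76), came Me1, the cytosolic malic enzyme that supplies NADPH for lipid synthesis, with 1.76 (SE 0.26). Osbpl3, a lipid-binding protein, lay higher by 1.34 and the microvillar actin-bundling protein gene Pls1 by 1.14. Leukocyte genes among the 12 were Cd48 (1.32, SE 0.13), Ms4a4b (1.35), Cd52 (1.23), Hcls1 (1.19), Aif1 (1.26) and the immunoglobulin heavy chain gene Ighm (1.32), the last uncertain because near-identical immunoglobulin transcripts can share its probes. Dimmer probe sets lay the other way for Ms4a4b (−0.14) and for Ighm (−0.37, −0.18 and −0.02), and the mean of all probe sets gave 0.60 for Ms4a4b, 0.36 for Ighm and 0.72 for Tcf21. Without dysplasia array 1 the difference was 0.84 for Ms4a4b and 0.87 for Osbpl3, and without tumor array 2 it was 0.82 for Ighm. The others were Lgals1, a galectin, at 1.31 and Tcf21, a mesenchymal transcription factor, at 1.26. Cd48, Cidea and Me1 were the only 3 genes with every tumor array at least 2-fold above every dysplasia array. With dysplasia array 2 left out, Me1, Osbpl3, Cd48 and Pls1 came under the threshold (adjusted p = 0.041, 0.0401, 0.0449 and 0.0449), but the only dysplasia array was then array 1 and the spread came from the tumor arrays alone.

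The 12 genes named as lower lay 1.64- to 2.9-fold lower on the tumor arrays, and 0 passed. Dnajc12, a co-chaperone, differed by −1.54 (SE 0.44), Saa3 by −1.43, the vasopressin receptor gene Avpr1a by −1.36, and Sdf2l1, of the unfolded protein response, by −1.14. The hepatocyte genes Rdh16f2, Slc22a7, Serpina7 and Serpina11 differed by −1.05, −1.02, −0.84 and −0.73. The transcription factor genes Foxa3 and Foxq1 differed by −1.03 and −1.02, and the cytokine receptor genes Il13ra1 and Il6ra by −0.80 and −0.72, while a dimmer probe set of Il6ra gave −0.07 and the mean of its probe sets −0.40. Dnajc12, Avpr1a, Rdh16f2 and Foxa3 came under the threshold without dysplasia array 2 (adjusted p = 0.0333, 0.0463, 0.0486 and 0.0463), again with the spread of the tumor arrays alone. Without dysplasia array 1 the differences were −0.87 for Dnajc12, −0.91 for Saa3 and −0.80 for Avpr1a, and without tumor array 1 that of Serpina7 was −0.53.

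**Figure D3:**
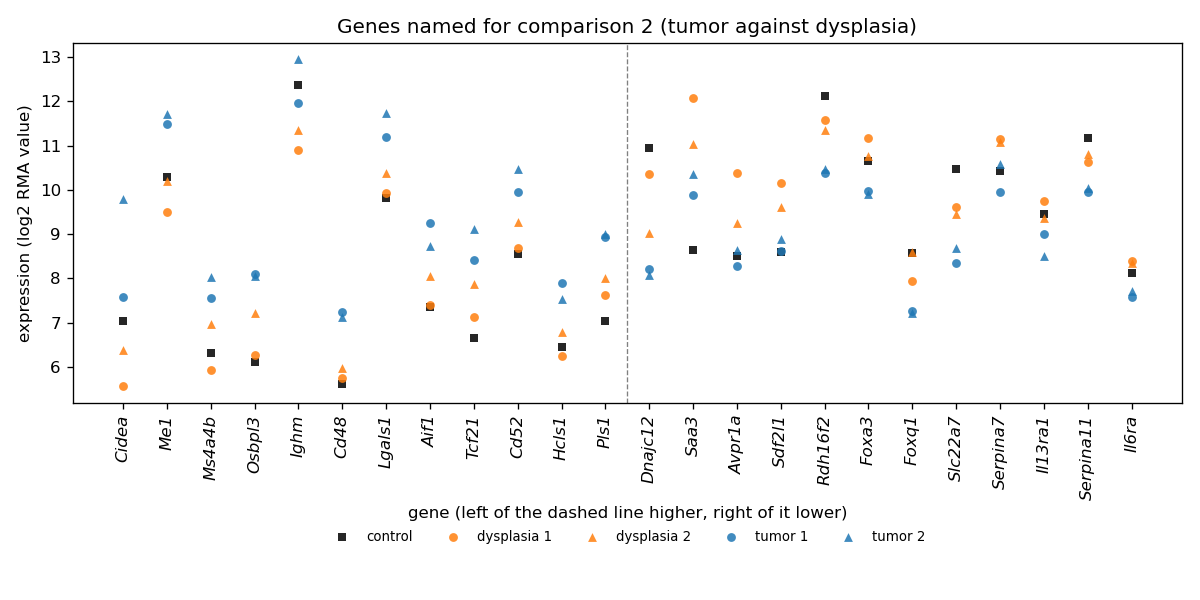
Expression (log2 RMA value, vertical axis) on each of the 5 arrays for the 12 genes named as higher and the 12 named as lower in comparison 2 (horizontal axis, divided by the dashed line). The control array is a black square, dysplasia arrays are orange and tumor arrays blue, with circles for array 1 and triangles for array 2 of a group. Me1 lies at 9.51 and 10.19 on the dysplasia arrays and at 11.50 and 11.72 on the tumor arrays, and Cd48 at 5.76 and 5.98 against 7.24 and 7.13.

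Among the metabolic lists, 5 of the 17 fatty acid synthesis genes passed when adjusted over the list alone and 0 over all genes. They were Me1, Thrsp (0.98), the elongase gene Elovl6 (0.89), Fasn (0.81) and Acacb (0.78), the last with −0.06 in a dimmer probe set. Genes of fatty acid oxidation and PPAR alpha targets rose by a mean of 0.28 (adjusted p = 0.000489, and adjusted p = 0.663 with an estimated correlation), with 16 of 20 higher and 0 past over all genes or when adjusted over the list alone. The peroxisomal gene Ehhadh lay at 1.31 and Pdk4, an inhibitor of pyruvate oxidation, at 1.04. The mean of the oxidation list was 0.17 without dysplasia array 1 (adjusted p = 0.159), 0.54 without tumor array 1 and 0.03 without tumor array 2 (adjusted p = 0.481). NRF2 and glutathione genes rose by a mean of 0.47 with 15 of 18 higher (adjusted p = 1.17e-08, and adjusted p = 0.387 with an estimated correlation), and 0 passed over all genes or when adjusted over the list alone. Cbr3 lay at 1.14, Abcc4 at 1.00 and Gsta4 at 0.90. Pericentral and beta-catenin target genes fell by a mean of 0.33 (adjusted p = 0.0178, and adjusted p = 0.663 with an estimated correlation), with 16 of 19 lower and 0 past over all genes or when adjusted over the list alone. The glutamate transporter gene Slc1a2 lay at −1.24 and Lgr5, a Wnt target, at −0.78. The pericentral mean was 0.07, in the reverse direction, without dysplasia array 1 (adjusted p = 0.608), −0.74 without dysplasia array 2 and −0.22 without tumor array 1 (adjusted p = 0.209).

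Immune cell lists moved in both directions in comparison 2, with 0 members past over all genes in each. Of 22 macrophage markers 20 lay higher, and Ms4a7 (1.05), Lyz2 (0.94), the signalling adaptor gene Tyrobp (0.81), Cd68 (0.78), Aif1 (1.26), C1qa and C1qc passed when adjusted over the list alone. The MHC class II list rose by a mean of 0.58 (adjusted p = 6.11e-12, and adjusted p = 0.443 with an estimated correlation), all 10 members lay higher, and 5 passed when adjusted over the list alone. H2-Aa lay at 1.08 and H2-Eb1 at 1.00. Interferon response genes rose by a mean of 0.39 (adjusted p = 1.61e-12, and adjusted p = 0.443 with an estimated correlation), with 25 of 28 higher and 0 past when adjusted over the list alone. Oasl2 lay at 0.80 and Ifit2 at 0.72. B and plasma cell markers rose by a mean of 0.31 (adjusted p = 0.0217, and adjusted p = 0.663 with an estimated correlation) with 0 past when adjusted over the list alone. Ighm lay at 1.32 and the B cell receptor gene Cd79b at 0.70. The B and plasma cell mean was 0.67 without tumor array 1, and reversed to −0.06 without tumor array 2 (adjusted p = 0.336). The call was lost without dysplasia array 2 (mean 0.29, adjusted p = 0.365) and with dim genes left out (mean 0.36, adjusted p = 0.24), although the mean was about as large. T and NK cell markers rose by a mean of 0.11 (adjusted p = 0.022, and adjusted p = 0.663 with an estimated correlation), with 13 of 22 higher and 0 past when adjusted over the list alone. Cd3g, a chain of the T cell receptor complex, lay at 0.81. That call was lost without dysplasia array 2 (mean 0.10, adjusted p = 0.371) and with dim genes left out (mean 0.04, adjusted p = 0.948). Neutrophil markers fell by a mean of 0.57 (adjusted p = 0.00681, and adjusted p = 0.663 with an estimated correlation), with 10 of 12 lower and 0 past when adjusted over the list alone. The calprotectin genes S100a8 and S100a9 lay at −1.75 and −1.58. The neutrophil mean was −0.06 without dysplasia array 1 (adjusted p = 0.223) and −1.09 without dysplasia array 2. The neutrophil call was lost with dim genes left out (adjusted p = 0.0643), although the mean was then −0.73.

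The remaining lists that passed held stress, plasma protein, matrix and endothelial genes, with 0 members past over all genes. In the unfolded protein response list Sdf2l1, Xbp1 (−0.69) and Pdia4 (−0.66) passed when adjusted over the list alone, and the chaperone gene Hspa5 lay at −0.55. The dimmest of 4 probe sets of Xbp1 gave 0.07. Acute phase genes fell by a mean of 0.56 with 21 of 22 lower (adjusted p = 1.49e-07, and adjusted p = 0.663 with an estimated correlation) and 0 past when adjusted over the list alone. Itih3 lay at −0.64. The acute phase mean was −0.04 without dysplasia array 1 (adjusted p = 0.159) and −1.07 without dysplasia array 2. Stellate cell and matrix genes rose by a mean of 0.48 with 23 of 24 higher (adjusted p = 4.65e-07, and adjusted p = 0.663 with an estimated correlation) and 0 past when adjusted over the list alone. The fibrillar collagen gene Col3a1 lay at 1.29 and Lrat, the retinol storage enzyme of stellate cells, at 0.99 (−0.03 in a dim probe set). The matrix mean was 0.86 without tumor array 1 and 0.10 without tumor array 2 (adjusted p = 0.174). Endothelial markers rose by a mean of 0.30 with 13 of 16 higher (adjusted p = 2.91e-05, and adjusted p = 0.663 with an estimated correlation) and 0 past when adjusted over the list alone. Pecam1 lay at 0.47 and the scavenger receptor gene Stab1 at 0.37. The endothelial mean was 0.08 without dysplasia array 1 (adjusted p = 0.145) and 0.52 without dysplasia array 2.

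The other 16 lists did not pass in comparison 2, with 0.0587 as the smallest adjusted p. Mean differences were 0.18 for bile acid genes, 0.17 for periportal genes, 0.15 for xenobiotic metabolism genes, 0.14 for male-biased genes, 0.14 for p53 response genes, 0.07 for cytokines and chemokines and 0.07 for cholesterol synthesis genes. They were −0.28 for immediate early genes, −0.13 for hepatocyte plasma proteins, −0.06 for fetal liver and liver tumor markers and −0.03 for circadian clock genes. The chemokine gene Ccl5 (1.03) and the hepatocyte regulator gene Foxa3 (−1.03) passed when adjusted over the list alone, and neither did over all genes. Clock genes again moved both ways, with 8 higher and 10 lower, which the list mean can hide. Median, mean and test differed in sign for bile duct markers (median −0.05, mean 0.04, test upward), cell division genes (−0.10, −0.02, upward), female-biased genes (−0.16, 0.02, downward), erythroid markers (−0.13, 0.07, downward) and adipose and pancreas markers (−0.09, 0.03, downward).

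Several of these 16 lists came under the threshold in comparison 2 with 1 array left out, where the other group alone gives the spread. With dysplasia array 2 left out these were periportal genes (mean 0.45, adjusted p = 0.0036), male-biased genes (0.37, 0.0345), p53 response genes (0.30, 0.00348), bile acid genes (0.53, 0.0003), xenobiotic metabolism genes (0.43, 6.64e-05) and cholesterol synthesis genes (0.21, 0.0213). Cell division genes (−0.29, 0.00333) and fetal liver and liver tumor markers (−0.39, 0.0453) did so downward. With dysplasia array 1 left out, cell division genes (mean 0.25, adjusted p = 8.44e-07), fetal liver and liver tumor markers (0.27, 0.00186), bile duct markers (0.41, 0.000778) and cytokines and chemokines (0.19, 0.000479) did so upward. Bile acid genes (−0.18, 0.00434), xenobiotic metabolism genes (−0.12, 0.0174) and hepatocyte plasma proteins (−0.20, 3.79e-06) then did so downward. Bile duct markers had a mean of 0.31 without tumor array 1 (adjusted p = 0.0179). Hepatocyte plasma proteins also came under the threshold, at means of −0.13 to −0.16, with the mean of all probe sets (adjusted p = 0.0352), with dim genes left out (0.00771), after quantile normalization again (0.0314), with the replicate block (0.0487), with the replicate numbers of 1 group exchanged in the block, a test chosen after the results were seen (0.0368), and without tumor array 1 (0.0188). Cytokines and chemokines did so with the mean of all probe sets (0.10, 0.0411) and after quantile normalization again (0.06, 0.0297). Bile acid genes (0.20, 0.024) and p53 response genes (0.15, 0.033) did so with the mean of all probe sets. With the numbers exchanged, 5 more lists came under it (periportal, bile acid, xenobiotic, p53 response and immediate early). Without tumor array 2, p53 response genes had a mean of 0.17 (adjusted p = 0.0481). Periportal genes had 0.27 (adjusted p = 0.0147) and immediate early genes −0.49 (adjusted p = 0.000659) without tumor array 2.

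With 0 genes called by limma in comparison 2, 527 genes had an unadjusted p under 0.05 (384 higher and 143 lower), against 910 by chance, and for 5917 genes (32.5%, chance 33.3%) the groups did not overlap. Camera with an estimated correlation and fry each called 0 of the 30 lists. The former also called 0 of 20 shifted lists in the simulations, so its count cannot tell shifted lists from unshifted ones. The count of called genes was 173 without dysplasia array 2, with the spread from the tumor arrays alone. The count of genes 2-fold apart was 10 and 332 without dysplasia arrays 1 and 2 and 65 and 30 without tumor arrays 1 and 2, in place of 3. That direction is fixed by the rule, which fewer arrays must meet once 1 is left out.

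Across the 18193 genes the log2 differences of both comparisons, which share the dysplasia arrays with opposite sign, correlated at r = −0.123, where genes are not independent replicates. With unchanged groups that share these arrays, 100 simulations gave a mean of −0.408 (−0.469 to −0.342). The covariance was −0.00883 against a simulated −0.0292 (−0.0351 to −0.0247), a difference of 0.0204. The simulations gave all arrays of a gene the same spread, a setting that with the group sizes fixes the mean simulated correlation. The real dysplasia arrays lay 0.416 apart and the tumor arrays 0.2445, so no conclusion is drawn from these differences. The correlation was −0.0908 without dysplasia array 1, −0.6 without dysplasia array 2, −0.0529 without tumor array 1 and −0.17 without tumor array 2. No gene passed in both comparisons, in which limma called 1 and 0. With the dysplasia arrays divided between the comparisons, a test chosen after the values were seen, the correlation was 0.26 with array 1 in comparison 1 and array 2 in comparison 2, and 0.373 the other way. The covariances were 0.0209 and 0.048. The negative correlation may thus come from the shared arrays, although each divided comparison had only 1 dysplasia array.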

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

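The tests in this part were chosen only after the result was seen, except that of a different preparation of tumor array 2.

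Some control probe sets, which no comparison uses, gave signals above those of the control array on some arrays. The Trpn spike-in lay 6.76 log2 units higher on tumor array 2 than on the control array, the poly-A spike-ins lay 3.06 higher there and below the control array on the other infected arrays (7.42 to 8.06 against 9.84), and the 18S ribosomal RNA probe sets lay 3.77 higher on the lowest infected array and 5.47 higher on the highest. Without tumor array 2, 11 of the 14 lists called in comparison 2 kept their direction and at least 50% of their mean shift, and the B and plasma cell, stellate cell and matrix, and fatty acid oxidation lists did not. Spike-ins are RNAs added to a sample and do not come from the liver. The Trpn spike-in lay at 11.39 on tumor array 2 and at 4.53 to 4.62 on the other arrays. Tumor array 2 thus differed from the others in its added RNA. The count of lists lay between the bounds set for the test. Whether a different preparation of this array shifted the lists therefore stays open, above all for those 3 lists. The control array differed in added RNA as well, with the poly-A spike-ins at 9.84 against 7.42 and 8.06 on the dysplasia arrays. In addition, every 18S probe set lay at least 2.23 log2 units lower on the control array than on the lowest infected array. Effects of a different preparation of the control array cannot be told apart from infection in comparison 1, because the control group has no other array. For the lists and the 18S signal, a biological difference between the livers stays open as untested.

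Most skeletal muscle markers lay higher on the control array than on the infected arrays, with Myh1 at 9.77 against 4.49 to 4.78 and Acta1 at 8.54 against 5.59 to 5.88. An array-wide shift of dim probe sets is argued against, since the median of the 34 muscle markers, 0.62 higher on the control array, stood at percentile 100 among 10000 random lists matched on mean level (central 95% from 0 to 0.13). These markers include the 12 genes of the size rule that drew attention to them, but the 22 others, with a median of 0.51, also stood at percentile 100 (central 95% from −0.03 to 0.14). The random lists draw unrelated genes, so these percentiles do not show how rare such a shift is in genes that vary together. Muscle tissue in the control sample may be the source, since of the 22 markers outside the size rule 90.9% were highest on the control array, against 24.6% of all genes. The fast myosin gene Myh4 lay only at 5.73 against 5.03 to 5.19, and Mb (myoglobin) and Neb were not highest on the control array, which leaves the kind of muscle unsettled. A change of these genes with infection was not tested apart from this, with 1 control array.

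Dysplasia array 1 lay 0.416 from dysplasia array 2 and 0.408 from tumor array 2, and the values of many lists rested on it. Degraded RNA could contribute. The difference between 3′ and 5′ probe sets was highest on dysplasia array 1 for 2 of the 3 control transcripts (Gapdh at 0.59 and Pcx at 3.7). Actb at 1.09 lay below the control array's 1.13, so the test over all 5 arrays did not decide. Among the 4 infected arrays, dysplasia array 1 was highest for all 3 transcripts. The other infected arrays lay at 0.88 to 0.99 for Actb, 0.34 to 0.45 for Gapdh and 2.86 to 3.1 for Pcx. Degraded RNA thus stays open. An exchange of labels with a tumor array was not decided either, since the distance to the nearest tumor array was 0.981 times that to dysplasia array 2. Dysplasia array 1 lay about equally far from every other array (0.408 to 0.423), so this ratio can say little about an exchange. Dysplasia array 2 lay nearer to tumor array 1 (0.188) than the tumor arrays lay to each other (0.2445). A difference of lesion or infection between the samples stays open as untested.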

How the results depend on the processing

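The crossed replicate block, the count without skeletal muscle markers, and the relation with an array left out or with divided dysplasia arrays, are tests chosen only after the results were seen. All genes named by the largest change kept their direction under every alternative run per gene. Single dimmer probe sets lay the other way for Rragd (−0.36) and Ckm (0.06) in comparison 1, and Ms4a4b (−0.14) and Ighm (−0.37, −0.18 and −0.02) in comparison 2. Comparison 1 called 1 gene. It called 2 (Myh1 and Acta1) with the mean of all probe sets, an intensity trend, the looser threshold of 0.1 or all 4 infected arrays. With all probe sets tested it called 2 probe sets, both of Myh1. It called 0 with dim genes left out, median centring, only control and dysplasia arrays or muscle markers left out, and 0 to 42 with 1 array left out. Leaving out dim genes or muscle markers removes Myh1 itself from the test. For the other changes in this part the cause was not tested. Comparison 2 called 0 genes by limma under every alternative (unadjusted p under 0.05 for 527), except 0 to 173 with 1 array left out. With 1 array left out, the spread comes from the other group of 2 arrays alone.

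The size count of 96 in comparison 1 was 59 with the mean of all probe sets, 425 at 1.5-fold, 214 with the tumor arrays, and 96 to 528 with 1 array left out; quantile normalization gave 54 higher and 31 lower against 71 and 25. Without muscle markers it was 84. The count of 3 in comparison 2 was 48 at 1.5-fold and 10 to 332 with 1 array left out. Leaving out an array can only keep or raise either size count. Called lists, 13 and 14, were 0 and 0 with an estimated correlation and with fry, and 12 to 20 and 14 to 20 with 1 array left out. The correlation of −0.123 was −0.19 with dim genes left out and −0.6 to −0.0529 with 1 array left out. Its sign was reversed with the dysplasia arrays divided, 1 in each comparison (0.26 and 0.373).

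Against the control, the tumor arrays gave reversed tests for acute phase proteins (mean 0.109) and fatty acid synthesis (0.301). With 1 array left out, reversed lists ranged in comparison 1 from −0.42 to 0.288 (bile acid) and −0.031 to 0.188 (fatty acid oxidation), and in comparison 2 from −0.386 to 0.272 (fetal liver and tumor markers), −0.735 to 0.067 (pericentral), −0.178 to 0.529 (bile acid), −0.119 to 0.427 (xenobiotic), −0.292 to 0.249 (cell division) and −0.062 to 0.674 (B and plasma cells).

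Same-numbered dysplasia and tumor arrays deviated in opposite ways (correlation −0.234 over 2 pairs), so the numbers were not taken to pair samples. The replicate block called 0 genes (unadjusted 480) and 15 lists in comparison 2. Crossed pairing called 0 genes (unadjusted 1043) and 20 lists. Dim probe sets, near the floor of the array signal, limit what can be seen of low genes.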

Other observations

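The genes below were chosen only after their values were seen, and the test of liver zones was chosen only after the result was seen. Replicates of a group differed in whole gene groups. On dysplasia array 1 all 22 acute phase genes lay higher than on dysplasia array 2, by a median of 0.49 log2 units, with Saa2 at 14.05 against 10.69 and the endotoxin receptor gene Cd14 at 12.06 against 8.25. Neutrophil markers were higher by a median of 0.75, with S100a8 at 10.39 against 7.38, and 24 of 29 cell division genes were higher, by a median of 0.47. Bile duct and progenitor markers were higher by a median of 0.49 on dysplasia array 1, and the stem and duct cell gene Prom1 lay at 9.43 there, 5.78 on dysplasia array 2, 6.50 and 8.31 on the tumor arrays and 5.29 on the control array. Ly6d lay at 11.99 on dysplasia array 1 and 7.61 to 9.22 elsewhere. The succinate receptor gene Sucnr1 lay at 6.42 on dysplasia array 1 and 10.57 to 11.19 on the other arrays, and the methyltransferase gene Inmt at 9.05 against 12.06 to 12.45.

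The tumor arrays differed from each other in stroma and plasma cell genes. Tumor array 2 exceeded tumor array 1 by a median of 0.62 for B and plasma cell markers and of 0.66 for stellate cell and matrix genes, with Jchain, the joining chain of secreted immunoglobulin, at 11.15 against 8.60 and Lum, a matrix proteoglycan, at 10.63 against 8.56. Interferon genes were lower on tumor array 2, with a median difference of −0.23. The epithelial cadherin gene Cdh1 lay at 9.19 on tumor array 2 and 8.86 on dysplasia array 1, and at 5.45 to 6.50 on the other arrays. The fetal liver genes Afp (5.28 to 5.54) and Gpc3 (6.27 to 6.52) stayed low on all 5 arrays. The clock output gene Dbp lay at 5.42 on the control array, 6.07 and 8.75 on the dysplasia arrays and 8.08 and 6.17 on the tumor arrays, and Nr1d2, a clock repressor, at 8.48, 8.49, 10.42, 10.18 and 9.39 in the same order.

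Dysplasia array 1 held the highest values of several beta-catenin targets, with Slc1a2 at 12.14 and Rhbg at 11.15 against 9.12 to 10.14 and 7.92 to 9.70 on the other arrays. Against the mean of the other 3 infected arrays the pericentral list was higher by a median of 0.63, percentile 100 among 10000 random lists matched on mean level. Such lists draw unrelated genes, while the pericentral genes varied together (estimated correlation 0.457). The percentiles here therefore do not show how rare such a shift is. A hypothesis is that periportal expression gave way to pericentral expression on this array, which may mark a focus with beta-catenin activity. The periportal list was lower, with a median of −0.39 (percentile 1.05), but so was the xenobiotic metabolism list, which shares Cyp1a2 and Cyp2e1 with the pericentral list, with a median of −0.4 (percentile 0.11), so the hypothesis was not decided.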
